A study of Oryza sativa Japonica Group with 5 samples.

How the data were processed

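Leaf RNA of rice (Oryza sativa, Japonica Group) was sequenced from wild type plants (3 libraries) and from plants of the mutant pls4 (2 libraries). Per the labels, total RNA was extracted with Trizol and libraries were made with a TruSeq RNA kit; the labels give leaf as the tissue, mesophyll cell as the cell type, and "knockdown" as the treatment of the mutant. No label gives the age of the leaf, the growth conditions, an inoculation, the gene that is altered in pls4, or whether replicates came from separate plants. The level of the altered gene is therefore not reported here, and the p-values measure the spread between these libraries, which may be partly technical.

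The deposited values are FPKM (fragments scaled by gene length and by sequencing depth), 1 file per library, per the file headers; the deposit itself calls them RPKM. Per the submitters' processing notes, TopHat2 version 2.1.1 was used and the genome build was IRGSP-1.0. The counting tool, gene annotation, gene lengths and filters are not given in the sources used here, and neither is any scaling between libraries. Each file lists the same 36475 loci, of which 35667 carry identifiers of the Rice Annotation Project form (Os, chromosome, g, number) and 808 carry XLOC identifiers and no gene name. FPKM are relative values: a rise of a few very abundant transcripts lowers the values of all others. The values summed to between 736527 and 758853 per library. Among loci with an FPKM of at least 5 in both libraries of a pair, at most 0.276% held equal values (to the decimals listed), so each file was treated as a library of its own.

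Read counts were not used here, and total depth is unknown. Ratios of low values (0.1 to 0.8) between libraries were used to estimate relative depth. This assumes that a low FPKM is a whole multiple of the value of 1 read. The assumption was not checked, since the counting tool is not given, and the simulated data below were built on it too. Wild type replicate 2 was 1.30 times as deep as replicate 1. The ratio to wild type replicate 1 was 0.99 for wild type replicate 3, 1.04 for pls4 replicate 1 and 1.04 for pls4 replicate 2. On simulated data with a depth ratio of 1.4, the method failed on a first simulation with denser counts, where it returned 0.99, and returned 1.39 on a simulation with sparser counts that was added after that failure. The relative depths are therefore tentative.

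The comparison was fitted with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a variance trend on expression and Benjamini-Hochberg adjustment. Loci with FPKM of at least 1 in at least 2 libraries were tested (19637 loci), and a call required an adjusted p under 0.05. Fold changes are pls4 minus wild type on the log2(FPKM + 1) scale, which understates the change of low genes; ± beside a fold change is its standard error, and ± beside an FPKM is the SD (n = 3 for wild type, n = 2 for pls4). Both groups entered a single fit without further terms. The procedure was tested on data simulated for pls4 against wild type over 18631 loci. It recovered 97% of 100 genes changed by 1 and 100% of 100 genes changed by 2 on the log2 scale. Of its calls, 7.51% were false, above the nominal level of 5%. The changed genes were drawn only from loci with a wild type FPKM of about 5 or more. Far fewer loci were changed than were called in the real data, and no shift between libraries was simulated. These rates therefore need not hold for lower loci or under another scaling.

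The files do not pair identifiers with names, and the RefSeq gene table used here (assembly ASM3414082v1) matched 1 of the 36475 identifiers. Gene symbols therefore come from lists that paired published symbols with identifiers. The first lists, fixed before the data were examined like the fixed design, alternatives and naming rule, held 99 pairs for defence, hormones, photosynthesis, senescence, wax, clock and heat shock. Further lists with 126 pairs were written after the correlations between libraries and the values of the most abundant loci had been seen, but before any gene was tested. Those loci included RBCS2 and an Lhcb1 gene with lower values in pls4, so the list of plastid and chlorophyll synthesis is not fully independent of these data. They cover chlorophyll synthesis, antioxidant enzymes, immune signalling, sugar, nitrogen, iron, phosphate, abscisic acid, ethylene, flowering, and markers of dividing, vascular, root and seed tissue. Each pair was checked by comparing its chromosome and relative gene order with the place of that symbol in the RefSeq table, with a tolerance of 0.05 of the chromosome. Of the first pairs, 44 agreed, 2 disagreed and were dropped, and 53 had a symbol that the table lacks. These 53, which include all Lhc, RBCS and PAL genes, the wax genes, PR1a, PR1b, NAP, Osh36, RCI1, KSL8, FKF1, WRKY28, WRKY30 and WRKY45, rest on pairs recalled from the rice literature, and their names were not checked here. Of the further pairs only the 98 that agreed were kept. Planned keyword lists (splicing, ribosome, resistance proteins and others) needed gene descriptions and were not analysed here. One gene of the flowering list is not reported here. Coordinates are not given because no annotation of the files' build was used here.

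Lists with at least 5 tested members were tested with limma's camera (preset correlation 0.01), with adjustment over the lists. Alongside it, camera was run with an estimated correlation, and fry, whose p tests whether the genes of a list move, on balance, in one direction and does not compare them with other genes. The genes named follow a fixed rule. Of the 12 loci with the largest changes in each direction, 2 are printed, since these lack names. For each list, up to 4 called members with the smallest adjusted p are named, or up to 2 of the most abundant where none was called. Named whatever their result are 10 genes (PR1a, PR1b, PBZ1, WRKY45, NH1, SGR, NAP, RBCS2, WSL4 and LHY). The rule also planned the most abundant member for markers of other tissues, which was not applied throughout. Genes detected in 1 genotype alone were defined after seeing the data, as a mean FPKM of at least 5 in that genotype and at most 0.1 in every library of the other.

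The fixed alternatives were other pseudocounts (0.1 and 0.01), other filters, 3 other scalings of the libraries, limma without trend or with robust variances, the replicate number as a block, and leaving out each library. Leaving out both libraries of number 1, and other thresholds for the loci detected in 1 genotype alone, were added later. Near-identical copies (the RBCS genes, Lhcb1 genes, PAL genes and clustered diterpene synthases) can share reads, and how the authors assigned such reads is not given in the sources used here, so the split between copies is uncertain. Intron retention, named in the title of the series, needs reads or exon-level values and was not analysed here.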

Results

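Gene expression in leaves was compared between wild type rice and the mutant pls4, which the series describes as affected in its response to sheath blight, a fungal disease of rice. The data are FPKM values from 3 wild type and 2 pls4 libraries. Between 18393 and 18538 loci per library reached an FPKM of 1. The 10 most abundant loci took 14.3% to 15.2% of all FPKM in the wild type libraries and 13.2% to 13.5% in the pls4 libraries. Wild type replicate 2 was tentatively estimated to be 1.30 times as deep as replicate 1, and the other libraries between 0.99 and 1.04 times; the absolute depth is unknown.

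Of 19637 loci tested, 2812 changed by at least 2-fold, 1397 of them higher and 1415 lower in pls4 (limma, Benjamini-Hochberg adjusted p under 0.05); with each library scaled by its median ratio, 1107 were higher and 1714 lower. Values of the groups did not overlap at 69.9% of the tested loci, against 20% by chance. Among the loci without a gene name here, Os09g0518200 rose from a mean FPKM of 0.207 to 276 (log2 fold change 7.85 ± 0.20) and Os06g0347100 from 0.143 to 214 (7.57 ± 0.16). Os06g0580100 fell from 782 ± 39 to 0.125 (log2 fold change -9.45 ± 0.10) and Os10g0506900 fell from 276 ± 15 to a listed value of 0 in both pls4 libraries. Spearman correlations over the tested loci were 0.986 to 0.992 within wild type, 0.988 between the pls4 libraries and 0.866 to 0.876 between genotypes. The first principal component held 91.1% of the variance and separated the genotypes. Without a limit on size, 10208 loci (52.0%) were called, 6566 higher and 3642 lower. Without pls4 replicate 2, 6653 were called, 3986 of them higher. The median fold change of all tested loci was 0.151, and when each library was instead scaled by its median ratio the share of higher calls went from 64.3% to 46.7%, with 4243 loci higher (53.0% after quantile normalization), so small changes have no secure direction.

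Of 12 genes of light-harvesting chlorophyll proteins, 9 fell, 3 did not pass the test and none rose; adjusted over the list alone, 12 fell. Lhcb1 (Os01g0600900), an antenna protein of photosystem II, went from 10800 ± 577 to 4997 ± 297 FPKM (log2 fold change -1.11 ± 0.14), and a further Lhcb1 gene (Os01g0720500) from 348 ± 124 to 38.4 ± 25.3 (-3.24 ± 0.44). Lhcb4 (Os07g0558400) changed by -0.81 ± 0.12 and Lhcb3 (Os07g0562700) by -0.58 ± 0.10. With the replicate block the calls of Lhcb4 and Lhcb3 were lost, and only 2 of the 12 light-harvesting genes were called lower. All 4 genes for the small subunit of Rubisco, the enzyme that fixes carbon dioxide, were called lower, also adjusted over the list alone. RBCS2 (Os12g0274700) went from 14013 ± 3751 to 5900 ± 1405 FPKM (log2 fold change -1.23 ± 0.27), RBCS4 (Os12g0292400) changed by -1.44 ± 0.20 and RBCS5 (Os12g0291400) by -1.65 ± 0.28. RBCS3 (Os12g0291100) changed by -0.65 ± 0.22, a call (limma, adjusted p = 0.0439) lost with both other pseudocounts, with no filter, after quantile normalization, with the replicate block, and without wild type replicate 2 or 3 or either pls4 library. In wild type replicate 1, RBCS2 stood at 9723 FPKM against 16673 and 15642 in the other two. Without pls4 replicate 2, 5 light-harvesting genes and 2 RBCS genes were called lower, and the call of RBCS2 was lost, as it was with no filter and with the replicate block; with median ratio scaling 12 light-harvesting genes were. After quantile normalization 4 and 2 were, the calls of RBCS2 and of Lhcb1 (Os01g0600900) were lost, both at -0.43, and RBCS3 stood at 0.02.

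Of 9 listed genes of chlorophyll synthesis and plastid function 6 fell, none rose and 3 did not pass the test. This list was written after lower values of RBCS2 and an Lhcb1 gene in pls4 had been seen, so it is not fully independent of these data. PORA (Os04g0678700), which makes chlorophyllide in the light, dropped from 379 ± 39 to 71.0 ± 0.9 FPKM (log2 fold change -2.39 ± 0.10). RCA (Os11g0707000), Rubisco activase, went from 822 ± 73 to 162 ± 47 (-2.36 ± 0.18). CHLD (Os03g0811100) and CHLI (Os03g0563300), subunits of magnesium chelatase, changed by -1.36 ± 0.13 and -0.83 ± 0.12. The third subunit, CHLH (Os03g0323200) (chosen after its values were seen), was at 311 ± 31 and 311 ± 75. The light-harvesting list (camera, adjusted p = 0.000204) and the chlorophyll synthesis list (camera, adjusted p = 0.00404) were the only 2 of 16 lists that stood apart from the other genes in limma's camera test with a preset correlation. Neither did so with an estimated correlation (adjusted p = 0.673 for both), and after quantile normalization the light-harvesting list had an adjusted p of 0.228.

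**Figure D1:**
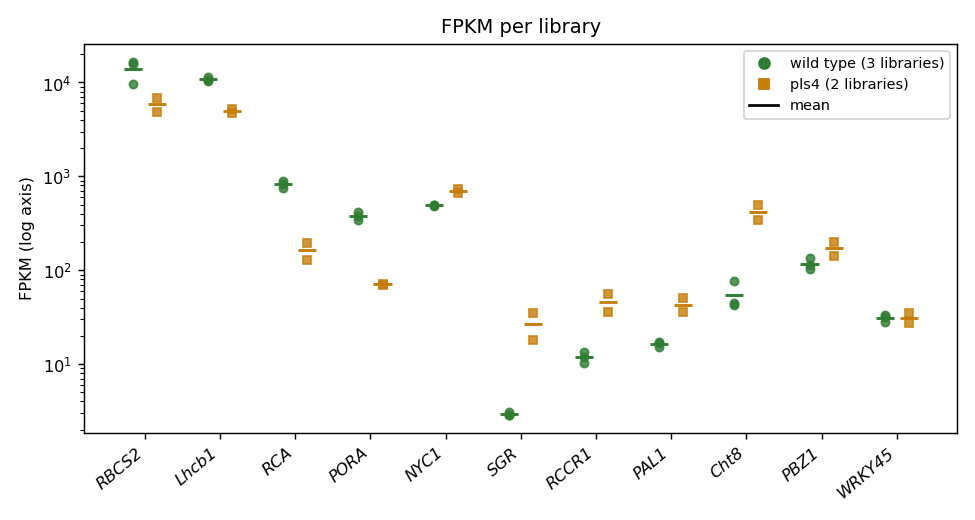
FPKM on a log axis of 11 genes in each of the 3 wild type libraries (circles) and 2 pls4 libraries (squares), with horizontal lines at the means; Lhcb1 is Os01g0600900. PORA falls from a mean of 379 to 71.0 FPKM and SGR rises from a mean of 2.95 to 18.1 and 35.4 FPKM, while WRKY45 has a mean of 31.1 in both genotypes.

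Of 10 tested genes of chlorophyll breakdown and leaf senescence, 7 rose, 1 fell and 2 did not pass the test; adjusted over the list alone the counts were 7 and 1. SGR (Os09g0532000, STAY-GREEN), which removes magnesium from chlorophyll, rose from 2.95 ± 0.12 FPKM to 18.1 and 35.4 in the 2 pls4 libraries (log2 fold change 2.74 ± 0.24). RCCR1 (Os10g0389200), red chlorophyll catabolite reductase, rose from 11.8 ± 1.6 to 46.4 ± 14.3 (1.86 ± 0.19). The senescence-associated genes Osh36 (Os05g0475400) and Osl2 (Os04g0614600) rose by 1.89 ± 0.16 and 1.16 ± 0.14. NAP (Os03g0327800), a NAC transcription factor that promotes senescence, went the other way, from 4.02 ± 1.15 to 1.81 ± 1.23 (limma, log2 fold change -0.88 ± 0.30, adjusted p = 0.0421), a call lost without wild type replicate 1 or 3, without pls4 replicate 1, with both other pseudocounts, with no filter and with the replicate block. With median ratio scaling, or without wild type replicate 2, 5 rose and 1 fell. Without wild type replicate 3, 5 rose and none fell. The list did not stand apart from other genes (camera, adjusted p = 0.242, and adjusted p = 0.673 with an estimated correlation). Its members moved, on balance, upward (fry, adjusted p = 0.0117), but most of the lists tested passed fry, so this is not particular to senescence genes.

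Defence genes, which the series names in its title, went both ways. Of 6 tested genes of pathogenesis-related proteins, 2 rose, 1 fell and 3 did not pass the test, with the same counts adjusted over the list alone. The chitinase gene Cht8 (Os10g0542900) rose from 54.7 ± 18.5 to 421 ± 112 FPKM (log2 fold change 2.94 ± 0.26), and the chitinase gene Cht1 (Os06g0726200) fell from 16.3 ± 5.5 to 4.18 ± 0.05 (-1.69 ± 0.23). PBZ1 (Os12g0555500), a probenazole-inducible PR10 protein, went from 117 ± 17 to 171 ± 43 (0.53 ± 0.17), a call lost under both median ratio scaling and quantile normalization and without wild type replicate 2 or 3 or pls4 replicate 2, among other alternatives. PR1a (Os07g0129200) stood at 1.31 ± 0.35 and 5.93 ± 6.39 FPKM (log2 fold change 1.20 ± 0.56, limma, adjusted p = 0.115; 2.32 and past the threshold without pls4 replicate 1), and PR1b (Os01g0382000) was under the filter with means of 0.343 and 0.920. Camera gave this list an adjusted p of 0.779, and an adjusted p of 0.978 with an estimated correlation.

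Regulators of immunity went both ways. Of 9 WRKY transcription factors, 4 rose, 1 fell and 4 did not pass, with the same counts adjusted over the list alone; 3 were higher and 2 lower under median ratio scaling, after quantile normalization, without wild type replicate 2 and without pls4 replicate 2. WRKY28 (Os06g0649000) rose by 1.26 ± 0.18, WRKY71 (Os02g0181300) by 0.96 ± 0.17 and WRKY30 (Os08g0499300) by 0.82 ± 0.12 on the log2 scale, while WRKY76 (Os09g0417600) fell from 5.49 ± 0.62 to 1.29 ± 0.60 FPKM (-1.52 ± 0.18). WRKY45 (Os05g0322900), a regulator of salicylate-dependent resistance, stood at 31.1 ± 2.7 and 31.1 ± 5.5 (limma, adjusted p = 0.984). NH1 (Os01g0194300), the rice homologue of NPR1, rose from 5.48 ± 0.72 to 10.2 ± 1.0 (0.80 ± 0.13). It was the 1 called gene of the 2 in the salicylate list, also adjusted over the list alone. PAL genes encode the entry enzyme of phenylpropanoid synthesis, and 3 of the 4 tested rose, also adjusted over the list alone. PAL1 (Os02g0626100) went from 16.4 ± 1.1 to 42.9 ± 10.4 FPKM (1.32 ± 0.15), PAL6 (Os04g0518400) changed by 1.12 ± 0.30 and PAL2 (Os02g0626400) by 0.74 ± 0.20; without wild type replicate 3, or without either pls4 library, 1 of these calls was left. Of 8 jasmonate genes 4 rose and 2 fell (4 and 3 adjusted over the list alone). The lipoxygenase gene RCI1 (Os12g0559200) fell from 34.8 ± 3.0 to 15.9 ± 0.3 (-1.08 ± 0.10) and the repressor gene JAZ8 (Os09g0439200) changed by -1.26 ± 0.19, whereas AOC (Os03g0438100) and JAZ12 (Os10g0392400) rose by 0.62 ± 0.11 and 1.06 ± 0.19. With median ratio scaling the jasmonate counts were 2 higher and 3 lower, and 1 higher and 2 lower without pls4 replicate 2. The median fold change of the jasmonate list was 0.27 and its mean 0.00, while camera placed it lower than other genes. Camera gave adjusted p = 0.898 for both the WRKY and the jasmonate list, and an adjusted p of 0.978 for each with an estimated correlation.

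Genes of diterpenoid phytoalexins, the antimicrobial compounds of rice, included the listed gene with the largest fold change. KSL7 (Os02g0570400), the synthase that leads to phytocassanes, was at 0.157 ± 0.061 FPKM in wild type and 36.4 ± 0.9 in pls4 (log2 fold change 5.02 ± 0.11). Listed genes with nearby identifiers, chosen after their values were seen, did not share this rise. CYP71Z6 (Os02g0570500) changed by 0.29 ± 0.10 and CPS2 (Os02g0571100) by -0.23 ± 0.08. CYP71Z7 (Os02g0570700) did not pass the test, and CYP76M8 (Os02g0569400) was under the filter with means of 0.447 and 0.055. KSL10 (Os12g0491800), which acts toward oryzalexins, rose from 0.0467 ± 0.0416 to 2.54 ± 0.64 (1.74 ± 0.15). KSL8 (Os11g0474800) fell from 0.953 ± 0.159 to a listed value of 0 in both pls4 libraries, and CPS4 (Os04g0178300) fell by 0.84 ± 0.21 on the log2 scale. Altogether 3 of 10 tested members rose and 3 fell, with the same counts adjusted over the list alone (camera, adjusted p = 0.959; adjusted p = 0.978 with an estimated correlation). Without either pls4 library 2 rose and 1 fell, and the call of CPS4 was lost, as it was after quantile normalization. Genes of cuticular wax and very-long-chain fatty acids gave 4 higher and 1 lower of 5, also adjusted over the list alone (camera, adjusted p = 0.710; adjusted p = 0.978 with an estimated correlation). ONI1 (Os03g0181500), a ketoacyl-CoA synthase, rose from 11.8 ± 2.2 to 24.7 ± 0.7 FPKM (1.02 ± 0.14), WSL1 (Os06g0598800) by 0.53 ± 0.12 and GL1-1 (Os09g0426800) by 0.42 ± 0.10, while GL1-2 (Os02g0621300) fell from 1.28 ± 0.05 to 0 and 0.02 in the pls4 libraries (-1.17 ± 0.12). WSL4 (Os03g0220100) changed by 0.32 ± 0.11, a call lost under median ratio scaling and quantile normalization, with the replicate block, with no filter, and without wild type replicate 1 or 2 or either pls4 library. The call of GL1-1 was lost with median ratio scaling and without either pls4 library, and there the list held 2 higher and 1 lower.

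**Figure D2:**
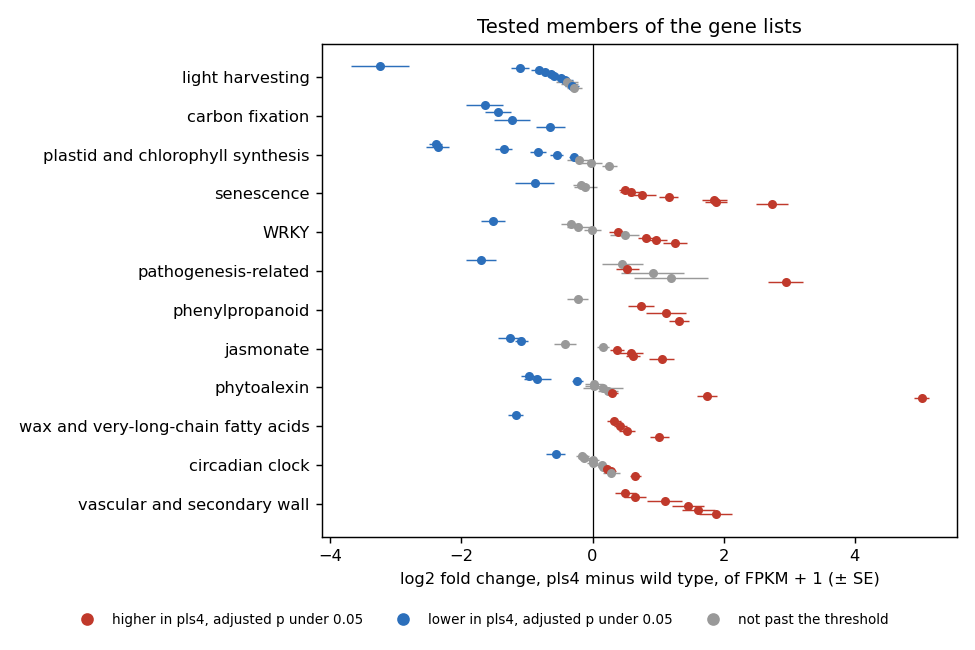
Log2 fold change of FPKM + 1 (pls4 minus wild type, point, with its standard error, bar) of every tested member of 12 gene lists; red and blue points passed an adjusted p of 0.05 and grey points did not. Light-harvesting and carbon fixation genes lie left of 0, senescence genes mostly right of 0, and KSL7 stands out among the phytoalexin genes at 5.02.

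Of 11 circadian clock genes, 3 rose, 1 fell and 7 did not pass the test, with 2 and 1 adjusted over the list alone; with median ratio scaling the counts were 1 higher and 3 lower, and without wild type replicate 2 or 3 or either pls4 library 1 was higher. FKF1 (Os11g0547000), a blue-light receptor, rose from 105 ± 2 to 165 ± 15 FPKM (log2 fold change 0.65 ± 0.08), LHY (Os08g0157600), a morning gene, went from 12.7 ± 1.2 to 8.39 ± 2.06 (-0.56 ± 0.15, a call lost without wild type replicate 1 or 3 or pls4 replicate 1), and GI (Os01g0182600) and PRR1 (Os02g0618200) changed by 0.28 ± 0.08 and 0.22 ± 0.07, calls that median ratio scaling removed, as did the replicate block and leaving out wild type replicate 2 or 3 or either pls4 library (camera, adjusted p = 0.898; adjusted p = 0.978 with an estimated correlation). Only 1 of 3 heat shock genes was tested: HSP101 (Os05g0519700) rose from 0.403 ± 0.032 to 3.95 ± 0.34 FPKM (1.82 ± 0.12), also adjusted over the list alone.

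Beside these groups, all 6 genes of secondary walls and vascular tissue rose, against 5 under median ratio scaling, 4 without pls4 replicate 2 and 3 without pls4 replicate 1. The cellulose synthases of the secondary wall CESA7 (Os10g0467800), CESA9 (Os09g0422500) and CESA4 (Os01g0750300) rose by 1.88 ± 0.26, 1.61 ± 0.25 and 1.46 ± 0.25, and BC1 (Os03g0416200) by 1.10 ± 0.27. BC1 stood at 4.75 FPKM in pls4 replicate 1 and 2.09 in replicate 2, and without replicate 1 its change was 0.65 and its call was lost. CESA4, the most abundant of these 4, reached 5.54 ± 2.66 FPKM. When an FPKM of at least 5 in at least 2 libraries was required, 2 genes of the list were tested. Both were higher, with a median change of 0.58. The list had a camera adjusted p of 0.120, and an adjusted p of 0.673 with an estimated correlation; with median ratio scaling the preset test gave 0.0386, and without pls4 replicate 2 it gave 0.0264. Of 9 genes of dividing cells 3 were tested. PCNA (Os02g0805200) did not pass, at 14.65 ± 0.63 FPKM in wild type and 12.54 ± 0.52 in pls4 (log2 fold change -0.21 ± 0.09). CDKB1;1 (Os01g0897000) rose from 8.83 ± 0.49 to 15.8 ± 0.5 FPKM (0.78 ± 0.09) and MCM2 (Os11g0484300) fell from 1.26 ± 0.18 to 0.135 ± 0.078 (-0.99 ± 0.13). Of the root genes LSI1 (Os02g0745100) had a call (0.42 ± 0.14) that both median ratio scaling and quantile normalization removed, as did the replicate block, testing with no filter and leaving out wild type replicate 2 or 3 or either pls4 library, and the seed storage gene GLUA2 (Os10g0400200) was at 4.31 ± 0.65 and 4.34 ± 0.64.

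With presence as a mean FPKM of at least 5 and absence as at most 0.1 in every library, 241 loci were detected in wild type alone and 79 in pls4 alone, 320 in all. Between libraries of the same genotype the highest such number in any pair was 2, and between genotypes it ranged from 88 to 263. Among loci with a mean FPKM of at least 5 in either genotype, 24.0% of 171 XLOC loci were of this kind against 2.07% of 13450 named by Os identifiers (Fisher's exact test over loci, two-sided, p = 4.81e-30; loci are not independent replicates). How the XLOC loci were defined is not given in the sources used here. If they were defined from these same reads, the test would not be independent of the pattern it measures. By chromosome, the share of expressed genes ranged from 0.55% on chromosome 7 to 4.29% on chromosome 12 and 5.41% on chromosome 11. The thresholds were set after seeing the data, and the count depends on them, being 160 when presence required an FPKM of 10 and 563 when it required 2.

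**Figure D3:**
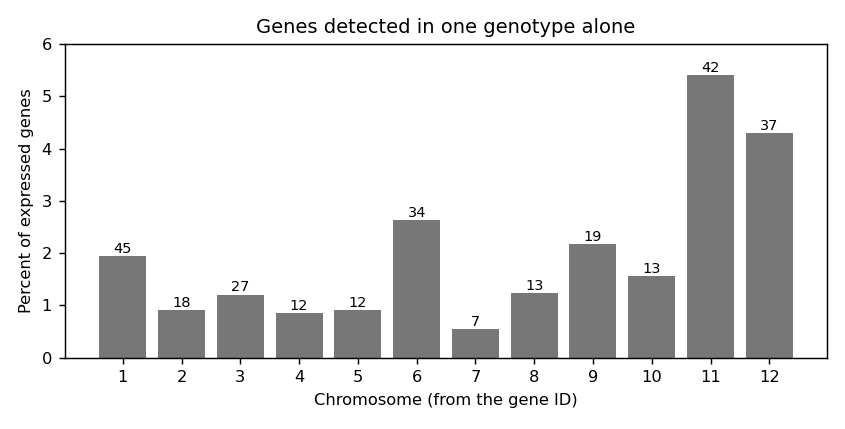
Percent of expressed genes with Os identifiers on each chromosome (read from the identifier) that were detected in 1 genotype alone; expressed means a mean FPKM of at least 2 over the 5 libraries, or detection in 1 genotype, and the number above each bar is the count of genes. Chromosomes 11 and 12 stand highest, with 42 and 37 genes.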

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

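Leaving out both libraries of number 1, and all alternatives for the loci detected in 1 genotype alone, were chosen after seeing the data. The count of genes changed by at least 2-fold kept within 1.5 times under each of the 17 alternatives fitted, and no gene called in both the original and an alternative fit changed sign. Among the 17, the filter to loci listed in all 5 files could change nothing, since every file lists the same loci. Of the direction splits, genes lower by at least 2-fold went from 1415 to 913 when an FPKM of 5 was required, with 13480 genes tested, and genes called higher without a size limit went from 6566 to 4243 under median ratio scaling, which moved the median fold change of all genes from 0.151 to -0.002. Leaving out 1 library gave 6653 (without pls4 replicate 2) to 10259 (without wild type replicate 1) changed genes, 3986 to 6780 higher genes and 2691 to 2942 genes changed by at least 2-fold; where 1 pls4 library was left, it was assumed to vary like the wild type. With the replicate number as a block, 7294 genes were called instead of 10208 and 2825 instead of 2812 by at least 2-fold, on 1 residual degree of freedom. The labels do not say that numbers are shared, so same-numbered libraries were not treated as pairs. The deviations of those libraries correlated at -0.095 and -0.138. With 2 pls4 libraries, whose deviations mirror each other, such correlations say little about pairing. The lists past the threshold numbered 2 as reported, 1 after quantile normalization, 0 with camera and an estimated correlation and 9 with fry, which asks a different question. RBCS3 turned from -0.65 to 0.02 after quantile normalization; the cause was not tested. Restricting Spearman correlations to loci with an FPKM of 5 gave medians of 0.834 between genotypes and 0.983 within pls4. Loci detected in 1 genotype alone numbered 160 and 563 with presence set at 10 and 2 and 325 to 338 without single libraries. Without both libraries of number 1, 8972 genes were called and 3113 by at least 2-fold. Over the named genes, 1331 of the alternative values kept their side of the threshold, 137 lost it, 5 gained it and 1 turned. The 1331 include 88 from the filter that could change nothing. Of the lost calls, 19 were without pls4 replicate 2, 17 without pls4 replicate 1 and 16 under the block. With 2 pls4 libraries the spread of that genotype rests on 1 difference, and low loci are limited by an unknown depth.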

Other observations

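The tests of large deletions, of gathering with neighbouring genes counted once, of harvest time and of green-cell share were chosen after the results they measure had been seen, and so was the definition of loci detected in 1 genotype alone. The test of gathering with every gene counted was set before its result.

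Of 8 genes of antioxidant enzymes 5 rose, 1 fell and 2 did not pass the test, against 3 higher and 1 lower with median ratio scaling. The ascorbate peroxidases APX1 (Os03g0285700) and APX2 (Os07g0694700) rose from 283 ± 7 to 484 ± 22 and from 1078 ± 80 to 1911 ± 119 FPKM, the catalase CATA (Os02g0115700) rose from 466 ± 64 to 954 ± 166, and the superoxide dismutase SODCC2 (Os07g0665200), which produces hydrogen peroxide, rose by 0.40 ± 0.08 on the log2 scale, a call that this scaling removed, as did quantile normalization. The ascorbate peroxidase APX8 (Os02g0553200), chosen after its values were seen, fell from 421 ± 70 to 268 ± 47 FPKM, and the list did not stand apart from other genes (camera, adjusted p = 0.376; adjusted p = 0.673 with an estimated correlation). Of 7 tested genes of immune receptors and signalling 4 rose and none fell, against 3 with median ratio scaling. The chitin receptor CEBIP (Os03g0133400) went from 42.6 ± 0.6 to 74.1 ± 5.6 FPKM, the kinase MPK3 (Os03g0285800) from 4.96 ± 0.54 to 10.8 ± 0.2 and SGT1 (Os01g0624500) from 40.6 ± 1.5 to 58.3 ± 4.6, while RAR1 (Os02g0535400) changed by 0.39 ± 0.12, a call lost with that scaling, after quantile normalization, with the replicate block, and without wild type replicate 2 or 3 or either pls4 library (camera, adjusted p = 0.376; adjusted p = 0.706 with an estimated correlation).

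Of 6 genes of flowering 3 fell and 2 did not pass the test. MADS14 (Os03g0752800), a floral identity gene, fell from 127 ± 11 to 14.1 ± 5.6 FPKM, the florigen HD3A (Os06g0157700) fell from 10.6 ± 3.4 to 2.38 ± 1.42 and HD1 (Os06g0275000) fell from 3.14 ± 0.15 to 0.485 ± 0.686 (camera, adjusted p = 0.215; adjusted p = 0.673 with an estimated correlation). In nitrogen assimilation the plastid glutamine synthetase GS2 (Os04g0659100) fell from 850 ± 97 to 329 ± 87, while the cytosolic GS1;2 (Os03g0223400) rose by 0.70 ± 0.12 on the log2 scale and the nitrate reductase NIA1 (Os08g0468100) from 63.9 ± 7.7 to 117 ± 2 FPKM (6 tested, camera adjusted p = 0.898; adjusted p = 0.978 with an estimated correlation). Of 8 genes of sugar and starch 4 rose and 2 fell: the sucrose transporter SUT2 (Os12g0641400) rose from 39.4 ± 1.6 to 70.0 ± 2.8, SWEET14 (Os11g0508600) from 1.31 ± 0.50 to 6.30 ± 0.62 and SUS2 (Os06g0194900) from 156 ± 17 to 249 ± 11, and AGPS2 (Os08g0345800) fell from 113 ± 8 to 80.5 ± 16.1 (camera, adjusted p = 0.586; adjusted p = 0.775 with an estimated correlation). None of the 8 was lower without wild type replicate 3 or without pls4 replicate 2, and 1 was lower without each of the other libraries; the call of AGPS2 was lost without wild type replicate 2 or 3 and without pls4 replicate 2. Of 6 tested genes of abscisic acid and dehydration, DREB1A (Os09g0522200) was higher (0.69 ± 0.20) and RAB16C (Os11g0454000) (-0.52 ± 0.18) and ABA8OX2 (Os08g0472800) (-0.22 ± 0.08) lower, calls that were lost without wild type replicate 3 and without pls4 replicate 2, among other alternatives (camera, adjusted p = 0.514; adjusted p = 0.835 with an estimated correlation). Of 3 tested ethylene genes EIL1 (Os03g0324300) rose by 0.68 ± 0.09, and ACO1 (Os09g0451400) and EIN2 (Os07g0155600) changed by 0.74 ± 0.20 and -0.33 ± 0.11, calls lost without either pls4 library, and that of EIN2 also without any 1 wild type library. Of 2 tested iron genes NAS3 (Os07g0689600) fell from 28.2 ± 2.9 to 14.7 ± 4.2, and none of 3 tested phosphate genes passed, PHT1;8 (Os10g0444700) standing at 81.0 ± 11.3 and 97.1 ± 14.0 and SPX2 (Os02g0202200) at 26.1 ± 1.9 and 23.0 ± 0.4. SPX2 did pass as lower under median ratio scaling (-0.35) and after quantile normalization (-0.34), against -0.18 in the main fit.

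The loci detected in 1 genotype alone raise the question of whether wild type and pls4 share a genetic background. Large deletions in pls4 would remove every gene in their span. However, 0% of the 221 lost genes with Os identifiers lay in uninterrupted runs of 5 or more wild type-expressed genes. The longest run had 4, 138 genes stood alone, and such genes occurred on all 12 chromosomes. At this limit, most lost genes thus stood alone. However, a gene counted as lost only at 0.1 FPKM or less in both pls4 libraries, so a small stray value breaks a run. Os06g0580100, the largest fall, was at 0.21 and 0.04 in pls4 and was not counted. Its identifier lies between those of lost genes. The limit of 5 was also set after the data were seen, and lies just above the longest run. The test therefore cannot decide on deletions, whether smaller or larger than this limit. Segments from another parent predict gathering, as do deletions that each took several genes. Genes detected in either genotype alone were pooled for this test. Genes within 5 identifiers of one another were first counted once. The fullest window of 200 consecutive identifiers, on chromosome 12, then held 9 of 222. The 95th percentile was 8 under 10000 random placements (permutation p = 0.0076). With every gene counted, the fullest window, on chromosome 11, held 14 of 279 against 8 (permutation p = 0.0001, the smallest that these placements can give). All genes counted in that window were detected in wild type alone. Its gathering therefore cannot tell deletions in pls4 from segments of another parent. Genes of the lists lie in these windows: RBCS3, RBCS4 and RBCS5, all called lower in pls4, in that on chromosome 12, and KSL8, MCM2 and RAB16C, all called lower, in that on chromosome 11, with RAB16B and RAB16D, which were not tested. A difference in background there could account for part of their lower values, which was not tested. A background that differs in segments, or throughout with more variable regions on chromosomes 11 and 12, may therefore contribute to this pattern and stays open. Deletions in pls4 stay open as well for the loci detected in wild type alone. So does regulation by the pls4 mutation itself, since genotype and background are confounded here.

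The breadth of the difference could come from leaves taken at different hours. The clock genes argue against a large difference in hour as the source of this breadth. Their median absolute fold change was 0.16, against a median of 0.43 and a 95th percentile of 0.69 for random lists matched on expression. The 11 genes thus differed less than comparable genes. The random lists carry the same broad genotype difference, so a smaller shift in hour is not excluded. Of the clock genes 3 rose, 1 fell and 7 did not pass the test. A difference in leaf age or physiological stage stays open as untested, because the labels do not give the age.

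The lower photosynthesis genes could reflect a smaller share of green cells, the more so as the vascular markers were higher. Such a loss would scale all of their genes alike, but over the 25 tested genes of light harvesting, Rubisco and chlorophyll synthesis the fold changes had an SD of 0.82 against a median standard error of 0.13, ranging from -3.24 to 0.25. Without the RBCS and Lhcb1 genes, whose copies can share reads, the SD was 0.71 and the median standard error 0.12 over 18 genes. A smaller share alone therefore does not account for the spread of these changes. How much it contributes to their shared fall (median -0.63) cannot be decided by this test, which measures spread only. Matched random lists were not compared here. With 52.0% of all tested loci called, a spread wider than the standard errors need not be particular to green-cell genes.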
